A study of Mus musculus with 75 samples.

How the data were processed

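Gene expression was measured in liver and epididymal white fat of male mice on 75 one-colour microarrays of a custom mouse design, 39 from liver and 36 from fat. Mice with an intact cannabinoid receptor 1 (CB1) gene and littermates lacking it received chow with 13% of energy from fat or a high-fat diet with 59.4% for 14 weeks from 2 months of age. Each mouse was then given vehicle or AM251, a CB1 inverse agonist, by oral gavage at 10 mg per kg in the late afternoon on 2 days, and tissue was taken at 10 in the morning of day 3. Tissue, diet, genotype and treatment define 16 groups of 3 to 5 arrays. In liver the high-fat knockout vehicle group held 4 arrays and the other groups 5. In fat the high-fat knockout vehicle group and the chow knockout AM251 group held 3 arrays each and the others 5. All 75 columns were used and 0 were left unassigned. Body weight and food intake, which the design text says were recorded, were not used here.

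The deposited values are probe set intensity values on a linear scale that the authors obtained with RMA (robust multi-array average, a background correction, normalization and summary of probes). The version of that software is not stated in the labels. The sample descriptions name virtual pools of vehicle arrays as references, but the values in the table are intensities per array and not ratios to those pools, so levels can be compared between genotypes and diets. Array medians ran from 25.9 to 28.7 in liver and from 44.3 to 48.0 in fat. The number of arrays per group limits the precision of every value.

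Of 38385 probe sets, 24543 were listed in the array annotation, 24478 of these with 1 gene symbol and 65 with several. The 13842 probe sets that were not listed and the 65 with several symbols were left out of the tests by gene and tested on their own. Each of 19147 genes was represented by its probe set with the highest mean in the tissue, a choice that mattered for the 3958 genes with more than 1 probe set. For differences between tissues it was the probe set with the highest mean over both, which for 572 genes was not the one used in liver or in fat. Entrez identifiers of 24237 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, which served only for names and for the order of neighbouring genes.

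Log2 intensities were fitted with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with 1 mean per group and all groups of a tissue in the fit, or all 16 groups for differences between tissues. Moderated two-sided tests of each contrast were adjusted over the 19147 genes by the Benjamini-Hochberg method, with a threshold of 0.05; 957 genes are expected by chance at an unadjusted p under 0.05. The contrasts were AM251 against vehicle within each tissue, diet and genotype, and the difference of that effect between genotypes, between diets in wild-type mice and between tissues in wild-type mice. Under vehicle they were knockout against wild-type mice and high-fat against chow diet in wild-type mice. Changes are given as log2 change ± standard error (SE).

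Fixed gene lists for metabolic, stress, immune, liver sex-biased and proliferation programmes and for markers of cell types were tested as sets. There were 32 lists, of which 31 had at least 5 measured genes; 3 genes were measured of the red blood cell list, which was not tested. Each list was tested with limma's camera on the moderated statistics with a preset correlation of 0.01 between genes and with a correlation estimated from the residuals, and with fry. List p values were adjusted over the 31 lists within a comparison. For list members, counts past the threshold are given over all genes and adjusted over the list alone.

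Named genes were chosen by rule. For AM251 effects and for genotype and diet effects under vehicle these are the 12 genes with the largest rise and the 12 with the largest fall past the threshold whose arrays in the first group all lay on the same side of the mean of the second group. For differences between effects they are the 8 largest in each direction. Up to 4 members of a described list with the smallest p, and always Cnr1, the gene of CB1, were added. Plotted genes, and genes carried from 1 comparison into another beside their values there, were chosen after their values were seen. Groups, contrasts, lists, rules and most of the alternative settings were fixed before the data were examined.

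The fit was tested on simulated data with the real genes' means and spreads, in which 200 genes were changed by known amounts. Noise was drawn independently for each gene and array, so the rates below do not cover correlated genes or single aberrant arrays. For the AM251 effect in livers of high-fat-fed wild-type mice, 70.1% of genes set to a log2 change of 0.5, 98.5% of those set to 1 and 100% of those set to 2 were recovered, and 7.73% of calls were false. For the genotype difference of that effect in liver, 31.3%, 86.6% and 100% were recovered at the same sizes. For the AM251 effect in fat of high-fat-fed knockouts 55.2%, 91% and 100% were recovered, and in fat of chow-fed wild-type mice 61.2%, 94% and 100%.

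Alternatives were the mean of all probe sets of a gene, quantile normalization, centring of array medians, leaving out genes below the median level, array weights, robust variance shrinkage, a fit of only the compared groups, the array number as a replicate block for tissue differences, and leaving out each array in turn. A fit without liver arrays 15 and 17 of chow-fed knockout vehicle mice, tests of each Cnr1 probe set and tests of lists with each array left out were added after the data were seen. The counts were also compared with up to 100 other splits of the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6.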

Results

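The data describe how a 2-day treatment with the CB1 inverse agonist AM251 changed liver and epididymal fat in lean and diet-induced obese mice, and which of these changes were seen in mice without the receptor. The 16 groups combine tissue, diet, genotype and treatment. Arrays of a tissue resembled each other closely: the mean correlation of an array with the other arrays of its tissue ran from 0.974 to 0.992 in liver and from 0.976 to 0.990 in fat. The lowest liver values were those of chow-fed knockout vehicle mice 17 and 15, at 0.974 and 0.983.

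Cnr1, which encodes CB1, was represented by 2 probe sets, and on neither were knockout arrays clearly lower than wild-type arrays under vehicle. In liver probe set 2 was dim in every group, with a mean log2 intensity of 2.54 ± 0.11 (SD, n = 5) in chow-fed wild-type vehicle mice. In fat, probe set 2 had a mean log2 intensity of 7.24 ± 0.56 (SD, n = 5) in chow-fed wild-type vehicle mice and 6.91 ± 0.43 (SD, n = 5) in chow-fed knockouts. In liver, where probe set 1 was the brighter, the means were 5.95 ± 0.17 (SD, n = 5) and 5.90 ± 0.21 (SD, n = 5). The position of the probes relative to the deleted sequence is not known here, so these levels say nothing about the knockout. AM251 left Cnr1 below the threshold in all 8 tests. In fat the log2 change of probe set 2 was -0.89 ± 0.32, adjusted p = 0.182 in high-fat-fed wild-type mice and -1.08 ± 0.32, adjusted p = 0.187 in chow-fed ones, where probe set 1 had 0.01 and 0.09. In liver the 4 values of probe set 1 lay between -0.23 and 0.01. Values of Cnr1 below are of probe set 2 within fat and of probe set 1 within liver and between tissues, unless both are given. The group means of probe set 1 ran only from 5.13 to 5.95 over both tissues, while probe set 2 was lower in liver than in fat. Whether probe set 1 measures receptor mRNA was not tested, so its liver values do not show that this mRNA was unchanged.

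AM251 lowered the genes that make cholesterol and fatty acids in the livers of high-fat-fed wild-type mice (n = 5 and 5), with Cnr1 probe set 1 at -0.02. Of 19 measured cholesterol synthesis genes and SREBP2 targets, 17 fell, 0 rose and 2 did not pass, with a list median of -1.29; 18 passed adjusted over the list alone. Examples are the farnesyl diphosphate synthase Fdps (-2.28 ± 0.22, adjusted p = 5.44e-09), the sterol sensor Insig1 (-1.66 ± 0.15, adjusted p = 2.82e-09), Nsdhl (-1.96 ± 0.20) and the HMG-CoA synthase Hmgcs1 (-1.34 ± 0.14). Of 23 genes of fatty acid and triglyceride synthesis, 15 fell and 0 rose, with a median of -1.24 and 18 adjusted over the list alone. Fatty acid synthase, Fasn, changed by -3.32 ± 0.34, adjusted p = 3.84e-08. The ATP citrate lyase Acly changed by -2.33 ± 0.30, the elongase Elovl6 by -1.99 ± 0.28 and the desaturase Scd1 by -2.08 ± 0.25. Both lists passed the set test with an estimated correlation, at an adjusted p of 0.000238 and 0.000299.

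Genes of fatty acid oxidation moved the other way in the same livers. Of 26 fasting and PPARα targets, 10 rose and 0 fell, with a median of 0.50. Adjusted over the list alone 18 rose and 1 fell, and the list passed with an estimated correlation (adjusted p = 0.00668). The acyl-CoA thioesterases Acot1 (2.29 ± 0.33, adjusted p = 1.7e-05) and Acot3 (1.65 ± 0.37) and the trifunctional protein subunit Hadhb (0.65 ± 0.091) are examples, of which Acot3 did not pass in a fit of only the compared groups (adjusted p = 0.103). Of 12 genes of gluconeogenesis and fasting hormones, 3 fell, 4 adjusted over the list alone (adjusted p = 0.0124 with an estimated correlation). They were the aminotransferases Got1 (-1.89 ± 0.22) and Tat (-1.26 ± 0.18) and the fructose bisphosphatase Fbp1 (-0.34 ± 0.067). Follistatin, Fst, fell with -2.62 ± 0.40, the urea cycle enzyme Ass1 with -0.85 ± 0.091 and the glutathione transferase Gstm3 with -2.00 ± 0.31. Abhd6, a hydrolase of the endocannabinoid 2-arachidonoylglycerol, rose by 0.97 ± 0.15.

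Among 22 drug-metabolism genes in these livers 5 rose and 3 fell, and the list as a whole did not pass (adjusted p = 0.34). The rises included Cyp2b10 (2.65 ± 0.56, adjusted p = 0.00425) and Cyp2c29 (1.28 ± 0.12, adjusted p = 5.44e-09). Of 10 male-biased liver genes 3 rose, 3 adjusted over the list alone, among them the steroid dehydrogenase Hsd3b5 (2.94 ± 0.63, adjusted p = 0.00474) and the oxysterol hydroxylase Cyp7b1 (1.79 ± 0.28). That list's adjusted p was 0.117 with an estimated correlation. The third, the anion transporter Slco1a1, had a change of 2.10, which was 1.18 without vehicle array 2 (adjusted p = 0.0549) and did not pass with only the compared groups (adjusted p = 0.234). The vehicle arrays of Hsd3b5 were spread over an SD of 2.56. Without vehicle array 2, at a log2 intensity of 4.42, the change was 1.90 (adjusted p = 0.0148), and the gene no longer passed in a fit of only the compared groups (adjusted p = 0.153). Hepatocyte markers had a median of -0.0012 over 13 genes with 2 lower, Ass1 and Arg1 (-0.38 ± 0.073), and the list's adjusted p was 0.709 with an estimated correlation. Of 22 cell cycle genes 1 rose and 1 fell (median -0.15, adjusted p = 0.253 with an estimated correlation). In all, 366 genes changed, 170 higher and 196 lower. Without vehicle array 2 the count was 233, and with array weights it was 625.

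**Figure D1:**
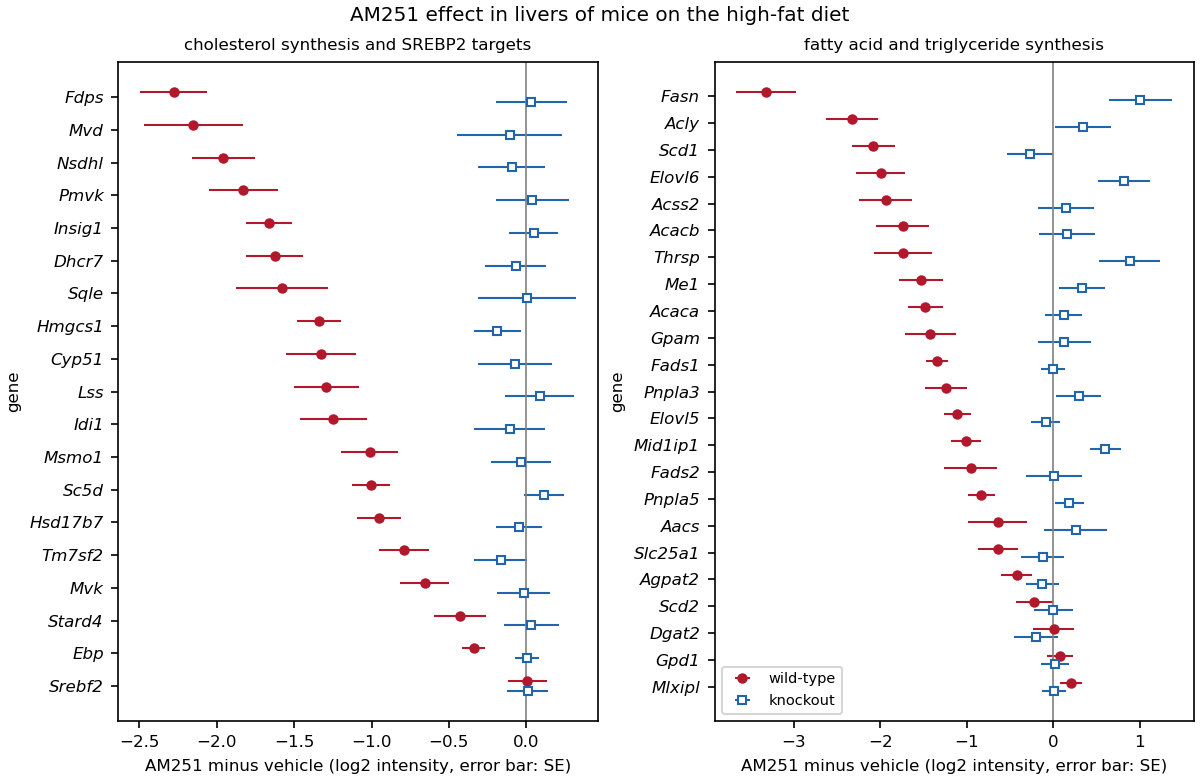
Log2 change with AM251 in livers of high-fat-fed mice for each measured gene of cholesterol synthesis and SREBP2 targets (left) and of fatty acid and triglyceride synthesis (right). Filled red circles are wild-type and open blue squares knockout mice, and error bars are SE. Most red circles lie to the left of zero, Fasn at -3.32 and Fdps at -2.28, while the blue squares of these 2 genes lie at 1.01 and 0.03.

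In livers of high-fat-fed knockout mice (n = 5 and 4), where Cnr1 was at 0.01, the few genes that passed were drug-metabolism genes. Of 22 of them 2 rose and 0 fell, 5 adjusted over the list alone, with a median of 0.30 and a set test that held with an estimated correlation (adjusted p = 0.00276), though not without vehicle array 44 (adjusted p = 0.0511). The 2 genes that rose, of cytochrome P450 enzymes, were Cyp2c55 (2.57 ± 0.33, adjusted p = 3.09e-05) and Cyp2c29 (1.18 ± 0.13, adjusted p = 9.4e-07). They were also the only 2 genes past the threshold among all genes, with 644 at an unadjusted p under 0.05 against 957 expected by chance. Cyp2b10 had a log2 change of 2.25 ± 0.60 with an adjusted p of 0.999 over all genes and 0.00414 adjusted over the list alone. Of the synthesis genes, Fasn had a log2 change of 1.01 and Fdps of 0.03, neither past the threshold. The fatty acid synthesis, oxidative phosphorylation, circadian clock and female-biased lists were higher, and the endothelial and interferon lists lower, with the preset correlation only (adjusted p from 0.332 to 0.611 with an estimated correlation).

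**Figure D2:**
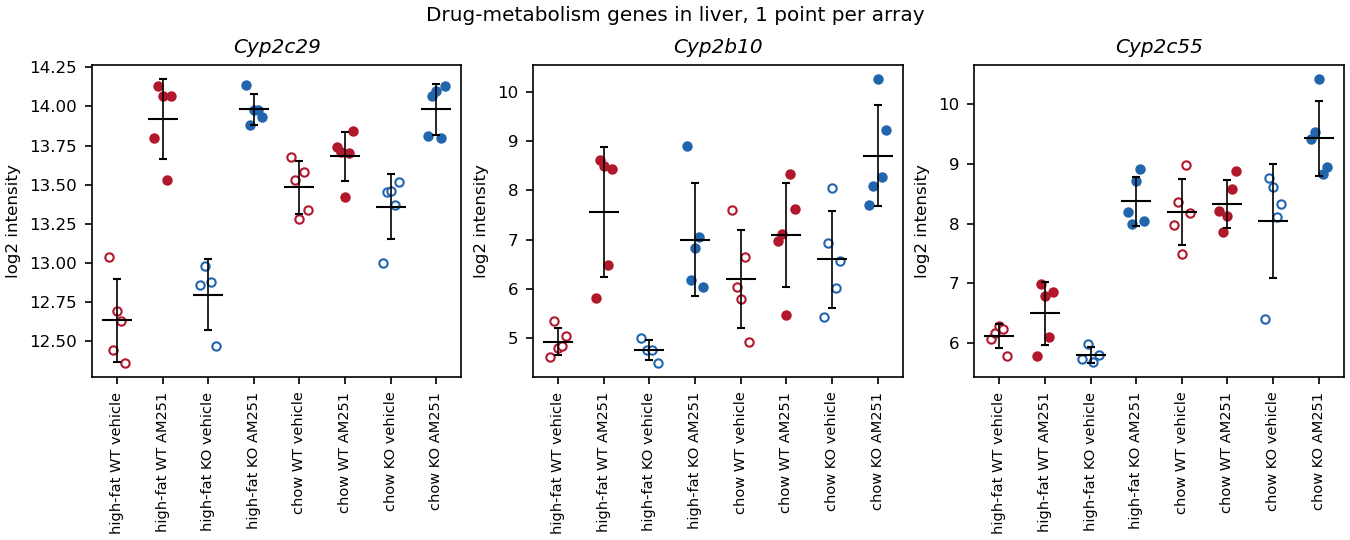
Log2 intensity of Cyp2c29, Cyp2b10 and Cyp2c55 in each liver array, by diet, genotype and treatment; red points are wild-type and blue points knockout arrays, open points vehicle and filled points AM251, and the bar and whiskers give the mean and SD. On the high-fat diet Cyp2c29 was higher with AM251 in both genotypes, by 1.28 and 1.18, and Cyp2c55 passed in knockouts, at 2.57.

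The AM251 effect in high-fat-fed livers differed between genotypes for 108 genes, 37 more positive and 71 more negative in wild-type mice, while Cnr1 had a difference of -0.03. Of the cholesterol synthesis genes 10 of 19 were more negative, 17 adjusted over the list alone, and of the fatty acid synthesis genes 14 of 23, 15 over the list alone. The lists' adjusted p were 0.000503 and 0.000462 with an estimated correlation. The differences were -4.33 ± 0.50, adjusted p = 3.63e-06 for Fasn, -2.67 ± 0.44 for Acly, -2.62 ± 0.49 for the lipogenic regulator Thrsp and -1.71 ± 0.21 for Insig1. Of the PPARα targets 5 of 26 were more positive, 13 over the list alone (adjusted p = 0.0234 with an estimated correlation, 0.0642 without knockout vehicle array 40), with Acot1 at 2.29 ± 0.48, adjusted p = 0.012. Gluconeogenesis genes were more negative for 2 of 12 (adjusted p = 0.0143 with an estimated correlation), with Got1 at -2.21 ± 0.32 and Tat at -1.54 ± 0.26. Of the drug-metabolism genes 3 of 22 were more negative (adjusted p = 0.2 with an estimated correlation), with Cyp2c55 at -2.18 ± 0.46, adjusted p = 0.0124. The differences of Cyp2c29 and Cyp2b10 were 0.10 and 0.39, with adjusted p of 0.971 and 0.978. The count was 66 without knockout AM251 array 46, 67 without knockout vehicle array 42 and 70 without wild-type vehicle array 4. It was 163 in a fit of only the compared groups and 230 with array weights.

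In livers of chow-fed mice fewer genes passed than on the high-fat diet in wild-type mice, but more in knockouts (24 against 2). In wild-type mice (n = 5 and 5) limma called 0 genes, with 2066 at an unadjusted p under 0.05 against 2154 on the high-fat diet and 957 expected by chance, and 7 without vehicle array 5. Cnr1 was at -0.23, Fasn at -0.27, Fdps at -0.21 and Cyp2c29 at 0.20. Markers of macrophages (median 0.24), of endothelial cells and interferon genes were higher with the preset correlation only, each with an adjusted p of 0.935 with an estimated correlation. In chow-fed knockouts (n = 5 and 5, Cnr1 -0.08) 24 genes passed, 18 higher and 6 lower. Among the higher were Cyp2c29 (0.62 ± 0.12, adjusted p = 0.0244) and Serpina6, the corticosteroid-binding globulin (0.72 ± 0.14, adjusted p = 0.0244). Cyp2b10 and Cyp2c55 had values of 2.11 and 1.38 that did not pass over all genes. Of 22 drug-metabolism genes 1 rose, 4 adjusted over the list alone, with a median of 0.21 (adjusted p = 0.632 with an estimated correlation). The fatty acid, bile acid, hepatocyte and exocrine pancreas lists were higher and the acute phase list lower with the preset correlation only, at 0.632 to 0.74 with an estimated one. The count of 24 depended on single arrays: it was 0, 7, 12 and 10 without AM251 arrays 22, 21, 23 and 24, and 1, 73, 7, 351 and 76 without vehicle arrays 15 to 19. It was 0 without arrays 15 and 17 together, with array weights or with only the compared groups, and 6 with the mean of all probe sets.

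For the genotype difference of the effect in chow-fed livers limma called 0 genes, with 1437 at an unadjusted p under 0.05, and Cnr1 at -0.15. Leaving out single arrays gave 1 gene (knockout AM251 array 23, wild-type vehicle arrays 1 and 5) or 2 (knockout vehicle arrays 15 and 17). The fatty acid synthesis list had a median difference of -0.37 with no member past the threshold (adjusted p = 0.718 with an estimated correlation).

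Diet changed the response of wild-type livers. The AM251 effect differed between high-fat and chow diet for 48 genes, 7 more positive and 41 more negative on the high-fat diet, with Cnr1 at 0.21. Cholesterol synthesis genes accounted for 10 of the more negative genes, 17 adjusted over the list alone, and fatty acid synthesis genes for 7, 17 over the list alone. Their adjusted p were 0.000848 and 0.0015 with an estimated correlation. Fasn differed by -3.05 ± 0.48, adjusted p = 0.000946, Insig1 by -1.73 ± 0.21, adjusted p = 9.93e-06 and Fdps by -2.07 ± 0.30. Acot1 (2.26 ± 0.46, adjusted p = 0.0146) was the PPARα target among 26 that was more positive over all genes, with 12 over the list alone (adjusted p = 0.0331 with an estimated correlation). That p lay between 0.053 and 0.104 without high-fat vehicle array 3 or 4, high-fat AM251 array 35 or 38, chow vehicle array 1 or 5, or chow AM251 array 8 or 10. Cyp2c29 differed by 1.08 ± 0.17. Of 12 gluconeogenesis genes 2 were more negative, with Got1 at -1.74 ± 0.31 (adjusted p = 0.016 with an estimated correlation for the list). The count was 31 without chow vehicle array 1 and 31 without chow AM251 array 13.

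In fat of high-fat-fed wild-type mice (n = 5 and 5, Cnr1 -0.89) AM251 raised several metabolic genes. The pantetheinase Vnn1 rose by 1.93 ± 0.36, adjusted p = 0.00598, the retinol-binding protein Rbp7 by 1.76 ± 0.25, adjusted p = 0.000743, and Pck1, the phosphoenolpyruvate carboxykinase, by 1.70 ± 0.25, adjusted p = 0.000891. The pyruvate dehydrogenase kinase Pdk4 rose by 1.64 ± 0.31 and the lipid droplet protein Plin5 by 1.10 ± 0.21. The acylglycerol acyltransferase Mogat2 (-1.86 ± 0.31, adjusted p = 0.00202), the glycogen synthase Gys2 (-1.86 ± 0.35) and the chemokine Cxcl10 (-0.87 ± 0.17) fell. Of 26 PPARα targets 5 rose, 7 adjusted over the list alone. Of 19 cholesterol synthesis genes 7 fell, 17 over the list alone, with a median of -0.59 and Fdps at -0.995 ± 0.18, adjusted p = 0.00581. Each of these 2 lists had an adjusted p of 0.0584 with an estimated correlation.

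Markers of other cell types were tested in the same fat samples. Of 17 endothelial markers 4 rose, 8 adjusted over the list alone, with a median of 0.25 (adjusted p = 0.165 with an estimated correlation). Of 29 macrophage markers 1 fell, 4 over the list alone, with a median of -0.43 (adjusted p = 0.345 with an estimated correlation). Of 20 inflammatory cytokines and chemokines 2 fell, 4 over the list alone (adjusted p = 0.283 with an estimated correlation). Of 13 lipolysis genes 2 rose, 4 over the list alone (adjusted p = 0.0838 with an estimated correlation). Of 22 cell cycle genes 5 fell adjusted over the list alone, and 2 of 23 fatty acid synthesis genes fell over all genes; their p were 0.345 and 0.655 with an estimated correlation. In all, 213 genes passed, 92 higher and 121 lower, or 131 higher and 105 lower with quantile normalization. The count was 54 and 106 without vehicle arrays 4 and 5, 632, 49 and 34 without AM251 arrays 34, 35 and 37, and 20 in a fit of only the compared groups. The 4 endothelial markers, Gpihbp1, Kdr, Robo4 and Sox18, and the macrophage marker Aif1 did not pass in that last fit (adjusted p from 0.173 to 0.23), nor without AM251 array 35 (0.0649 to 0.181) or 37 (0.0686 to 0.268), and all but Gpihbp1 did not pass without vehicle array 1 (0.0581 to 0.131) or 4 (0.0518 to 0.118). Of the other genes named, Pck1, Pdk4, Plin5, Gys2, Cxcl10 and Fdps did not pass in it, and each of these other genes passed without any 1 array.

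In fat of high-fat-fed knockouts (n = 5 and 3, Cnr1 -0.18) limma called 0 genes, with 712 at an unadjusted p under 0.05, and 1 without vehicle array 42. Rbp7 was at -0.78 and Pck1 at -0.62, and Fdps at 0.13. Oxidative phosphorylation, PPARα and interferon lists were lower and the cholesterol synthesis list higher (median 0.18) with the preset correlation only, each with an adjusted p of 0.688 with an estimated correlation. The effect differed between genotypes for 78 genes, 42 more positive and 36 more negative in wild-type mice. Rbp7 (2.54 ± 0.38, adjusted p = 0.0022) passed in every fit with 1 array left out. Pck1 (2.32 ± 0.38, adjusted p = 0.00725) passed in every such fit except the one without knockout vehicle array 43 (adjusted p = 0.0632). Cnr1 differed by -0.71. Of 19 cholesterol synthesis genes 1 was more negative, 15 adjusted over the list alone (adjusted p = 0.0693 with an estimated correlation). Of 26 PPARα targets 2 were more positive, 8 over the list alone (adjusted p = 0.0551 with an estimated correlation). The count of 78 moved with many arrays. It was 130, 22, 11 and 18 without knockout AM251 arrays 45, 46, 48 and 50, and 10, 1 and 30 without knockout vehicle arrays 42 to 44. It was 14 and 41 without wild-type vehicle arrays 4 and 5, and 279, 11 and 12 without wild-type AM251 arrays 34, 35 and 37. It was 294 with array weights, 153 without genes below the median level and 39 with only the compared groups.

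In fat of chow-fed mice few genes passed. In wild-type mice (n = 5 and 5, Cnr1 -1.08) limma called 0 genes, with 2559 at an unadjusted p under 0.05 against 2570 on the high-fat diet and 957 expected by chance. Leaving out vehicle arrays 1 and 3 gave 2 and 11 genes, and leaving out AM251 arrays 10 and 13 gave 6 and 2. The cholesterol and fatty acid synthesis lists had medians of -0.35 and -0.46, with 4 and 3 members lower adjusted over the list alone (adjusted p = 0.549 with an estimated correlation for both). Macrophage markers had a median of 0.26 (adjusted p = 0.753 with an estimated correlation). In knockouts (n = 3 and 5, Cnr1 0.24) 3 genes rose. They were Fdps (1.41 ± 0.21, adjusted p = 0.00249), the acetyl-CoA carboxylase Acacb (1.75 ± 0.31, adjusted p = 0.0271) and Tmem242 (0.76 ± 0.14, adjusted p = 0.0325). The count was 0 without AM251 array 23 and 1 without vehicle array 17 or 19, and Fdps and Tmem242 did not pass in a fit of only the compared groups (adjusted p = 0.0612 and 0.215). Of 19 cholesterol synthesis genes 1 rose, 5 adjusted over the list alone, and of 23 fatty acid synthesis genes 1 rose, 6 over the list alone. The medians were 0.40 and 0.37 (adjusted p = 0.123 with an estimated correlation for both). Oxidative phosphorylation genes had a median of 0.18 (adjusted p = 0.132 with an estimated correlation).

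The effect in chow-fed fat differed between genotypes for 1 gene, Fdps (-1.91 ± 0.28, adjusted p = 0.00142), which passed in every fit with 1 array left out; Cnr1 differed by -1.32 by probe set 2 and 0.38 by probe set 1. Cholesterol and fatty acid synthesis genes had median differences of -0.82 and -1.01, with 16 and 15 more negative in wild-type mice adjusted over the list alone (adjusted p = 0.0919 with an estimated correlation for both). The number of genes was 5 and 2 without knockout AM251 arrays 20 and 23 and 75, 27 and 7 without knockout vehicle arrays 16 to 18. It was 12, 19 and 15 without wild-type vehicle arrays 1, 3 and 5, and 34, 2, 4 and 3 without wild-type AM251 arrays 10, 12, 13 and 14. It was 16 with the mean of all probe sets, 10 without genes below the median level, 9 with array medians centred, 5 with only the compared groups and 2 with array weights. Between diets the effect in wild-type fat differed for 0 genes by limma, with 2001 at an unadjusted p under 0.05 and Cnr1 at 0.19. Leaving out AM251 array 34 of the high-fat group gave 32 genes and AM251 array 36 of that group 1. Without AM251 array 10 of the chow group the count was 4. High-fat vehicle arrays 3 and 6, high-fat AM251 array 33 and chow vehicle array 3 gave 2 each. Macrophage markers had a median difference of -0.63, with 10 of 29 more negative on the high-fat diet adjusted over the list alone (adjusted p = 0.396 with an estimated correlation).

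**Figure D3:**
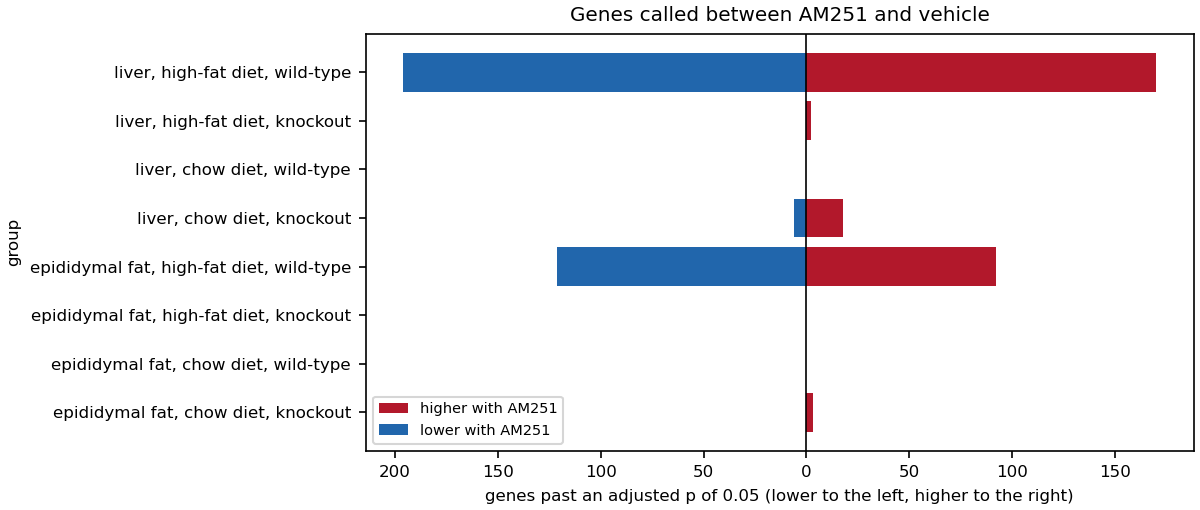
Number of genes higher and lower with AM251 in each tissue, diet and genotype at an adjusted p under 0.05. The bars reach 170 higher and 196 lower in livers of high-fat-fed wild-type mice and 92 and 121 in their fat. The count in fat was 20 in a fit of only the compared groups, and the 24 genes in livers of chow-fed knockouts fell to 0 without AM251 array 22.

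Liver and fat of high-fat-fed wild-type mice responded differently for 329 genes, 153 more positive and 176 more negative in fat, or 188 and 126 with quantile normalization, with Cnr1 at 0.02 by probe set 1 and -0.86 by probe set 2 (unadjusted p = 0.89 and 0.0117). Of 12 gluconeogenesis genes 4 were more positive in fat, 4 adjusted over the list alone (adjusted p = 0.00444 with an estimated correlation). They included Got1 (1.68 ± 0.29), Tat (1.36 ± 0.22) and Pck1 (2.02 ± 0.32, adjusted p = 9.79e-05). Of 23 fatty acid synthesis genes 9 were more positive and 1 more negative in fat, with Acacb at 2.67 ± 0.42, adjusted p = 7.84e-05 and Scd1 at 2.18 ± 0.27. Of 19 cholesterol synthesis genes 5 were more positive, with Hmgcs1 at 1.22 ± 0.20 and Nsdhl at 1.37 ± 0.29. The adjusted p of these lists was 0.107 and 0.169 with an estimated correlation. Cyp2c29 (-1.40 ± 0.17, adjusted p = 1.09e-07), Cyp2b10 (-2.70 ± 0.61) and Abhd6 (-1.08 ± 0.19) were more negative in fat. A difference between tissues can come from a change in either. Got1, Tat, Scd1, Hmgcs1 and Nsdhl had fallen in liver, and Cyp2c29, Cyp2b10 and Abhd6 had risen there, as given above. For these genes the difference does not show an opposite change in fat. Pck1 had risen in fat. The count was 202 and 208 without liver vehicle arrays 2 and 4, 495, 219 and 173 without fat AM251 arrays 34, 35 and 37, and 188 with only the compared groups. On chow 4 genes differed, all more positive in fat. Among them were Vmn2r96 (1.10 ± 0.18, adjusted p = 0.00211), a vomeronasal receptor, Psors1c2 (0.60 ± 0.11) and Tex37 (0.77 ± 0.15), with Cnr1 at 0.32 by probe set 1 (adjusted p = 0.317) and -1.12 by probe set 2 (unadjusted p = 0.00119). That count was 7 and 151 without liver vehicle arrays 4 and 5, and 8 without liver AM251 array 10. It was 7, 7 and 8 without fat vehicle arrays 1, 3 and 4, and 81 and 12 without fat AM251 arrays 10 and 13. It was 1 without genes below the median level and 1 with only the compared groups.

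Under vehicle, male-biased liver genes were higher and female-biased ones lower in livers of high-fat-fed knockouts (n = 4) than in those of wild-type mice (n = 5), with Cnr1 at -0.02. Of 10 male-biased genes 4 were higher and 0 lower in knockouts, 8 adjusted over the list alone, with a median of 1.13. Of 12 female-biased genes 4 were lower, 5 over the list alone, with a median of -0.49. Both lists passed with an estimated correlation (adjusted p = 0.0111 for each, and at most 0.0345 in the 9 fits with 1 array left out). The difference was not seen throughout: the male-biased median was 0.15 under AM251 on that diet. On chow it was -0.11 under vehicle and -0.35 under AM251. The female-biased medians of these 3 pairs were -0.083, 0.036 and 0.15. The AM251 and diet effects on these genes given for high-fat-fed wild-type livers use the same 5 wild-type vehicle arrays. Wild-type vehicle array 2 lay apart on these genes, and without it the difference of Slco1a1 went from 2.48 to 1.56. Slco1a1 did not pass without knockout array 44 (adjusted p = 0.0532) or with only the compared groups (adjusted p = 0.175). Cyp7b1 (1.86 ± 0.29, adjusted p = 0.000464) was higher, and the cytochrome Cyp2b9 (-4.61 ± 0.74, adjusted p = 0.00053) lower. Hsd3b5 (3.82 ± 0.67, adjusted p = 0.00139) was higher, with an adjusted p of 0.0884 when only the compared groups were fitted. Genes of lipid storage that mark adipocytes were lower as well: 4 of 16 adipocyte markers fell, 5 over the list alone (adjusted p = 0.0217 with an estimated correlation, 0.0533 without wild-type array 5). Among them were the lipid droplet protein Cidec (-2.28 ± 0.45), the fatty acid transporter Cd36 (-1.85 ± 0.34, adjusted p = 0.00185) and the nuclear receptor Pparg (-1.19 ± 0.18). Cidea, another lipid droplet protein, differed by -3.24 ± 0.52, the acyltransferase Mogat1 by -2.31 ± 0.34 and the vasopressin receptor Avpr1a by 1.60 ± 0.29. Fatty acid synthesis genes were lower for 4 of 23, 11 over the list alone, and PPARα targets for 6 of 26 (adjusted p = 0.198 and 0.34 with an estimated correlation). In all 228 genes differed, 92 higher and 136 lower, or 138 higher and 86 lower with array medians centred. The count was 96 and 75 without knockout vehicle arrays 42 and 44, 80 and 117 without wild-type vehicle arrays 2 and 4, and 588 with array weights.

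**Figure D4:**
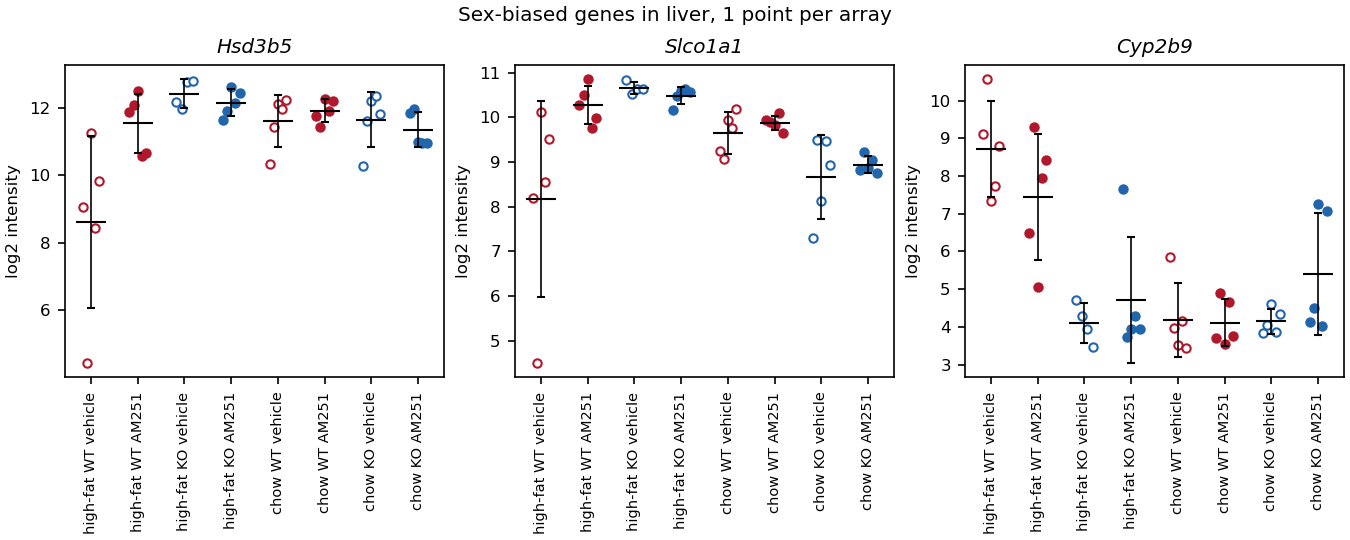
Log2 intensity of the male-biased genes Hsd3b5 and Slco1a1 and the female-biased gene Cyp2b9 in each liver array, by diet, genotype and treatment; red points are wild-type and blue points knockout arrays, open points vehicle and filled points AM251, and the bar and whiskers give the mean and SD. Open red points on the high-fat diet are spread widely for Hsd3b5 (SD 2.56), with array 2 lowest at 4.42, and Cyp2b9 was lower in knockouts than in wild-type mice given vehicle on that diet (-4.61).

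In chow-fed vehicle livers 1297 genes differed between genotypes (n = 5 and 5), 563 higher and 734 lower in knockouts, with Cnr1 at -0.05. The metallothionein Mt1 (2.79 ± 0.57, adjusted p = 0.00197) and the chemokine Ccl6 (0.96 ± 0.19) were higher. The Golgi protein Golga4 (-1.30 ± 0.18, adjusted p = 2.12e-05), the lipoprotein gene Apob (-1.45 ± 0.33) and Mlxipl, which encodes the glucose-responsive factor ChREBP (-0.66 ± 0.13), were lower. Of 18 acute phase genes 1 was higher, 6 adjusted over the list alone, and of 29 macrophage markers 3 were higher, 7 over the list alone. The adjusted p of both lists was 0.732 with an estimated correlation. This difference rested on few arrays. Without knockout vehicle array 17 the count was 595, and without array 18 it was 1991. It was 154 without arrays 15 and 17, of which 141 were among the 1297, 276 with array weights, and 3 with only the compared groups. None of the 5 genes named passed in that last fit. Arrays 17 and 15 were also the liver arrays with the lowest mean correlation with the rest.

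In fat of high-fat-fed mice given vehicle, markers of macrophages and inflammatory genes were lower in knockouts (n = 3) than in wild-type mice (n = 5), with Cnr1 at 0.20. Of 29 macrophage markers 23 were lower and 0 higher, 24 lower and 1 higher adjusted over the list alone, with a median of -1.09 (adjusted p = 0.0423 with an estimated correlation). The osteoclast-type proton pump subunit Atp6v0d2 (-4.93 ± 0.64, adjusted p = 1.05e-05), the elastase Mmp12 (-4.49 ± 0.60), the lipid receptor Trem2 (-3.92 ± 0.54) and the integrin Itgax (-3.31 ± 0.47) are among them. Of 20 inflammatory cytokines and chemokines 13 were lower, 14 over the list alone (adjusted p = 0.0423 with an estimated correlation), with Ccl2 at -3.02 ± 0.39. Of 22 cell cycle genes 17 were lower, 20 over the list alone (adjusted p = 0.049 with an estimated correlation), with the thymidine kinase Tk1 at -1.41 ± 0.22. Higher in knockouts were 5 of 13 lipolysis genes, with the triglyceride lipase Pnpla2 at 0.61 ± 0.10, and 5 of 12 gluconeogenesis genes with 1 lower, with Pck1 at 2.03 ± 0.29, adjusted p = 2.15e-05 (adjusted p = 0.0423 and 0.00947 with an estimated correlation). Of 33 genes of oxidative phosphorylation 14 were higher and of 11 mesothelial markers 8, at adjusted p of 0.164 and 0.15 with an estimated correlation. Without knockout array 43 the p of the macrophage, inflammatory, cell cycle and lipolysis lists was 0.0684 with an estimated correlation, and without wild-type array 1 or 5 it lay between 0.0501 and 0.061. Without wild-type array 3 it was 0.0539 and 0.0503 for the inflammatory and lipolysis lists, and without knockout array 44 it was 0.051 and 0.0635 for the inflammatory and cell cycle lists. The leptin gene Lep was lower (-1.28 ± 0.28), as was Cnr2, the gene of the other cannabinoid receptor (-1.31 ± 0.30). In all 3048 genes differed, 1382 higher and 1666 lower, and 1895 did without knockout array 44.

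On chow the same comparison in fat gave 11 genes, 4 higher and 7 lower in knockouts (n = 5 and 5), with Cnr1 at -0.33 (adjusted p = 0.794). The interleukin receptor Il17ra (0.93 ± 0.15, adjusted p = 0.00651) and the small GTPase Rab33a (0.53 ± 0.089) were higher and passed in every fit with 1 array left out. The count was 34, 3, 2 and 4 without knockout arrays 15, 17, 18 and 19, 5 and 6 without wild-type arrays 2 and 4. It was 17, 21, 40 and 20 with the mean of all probe sets, without genes below the median level, with array weights and with only the compared groups. Of the 31 lists, 5 passed with the preset correlation and 0 with an estimated one, the smallest adjusted p being 0.275.

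The high-fat diet itself changed both tissues of wild-type vehicle mice (n = 5 and 5). In liver 323 genes differed, 212 higher and 111 lower on the high-fat diet, with Cnr1 at -0.10. Cyp2b9 (4.53 ± 0.70, adjusted p = 0.000166), Cidea (2.87 ± 0.49), the hormone Fgf21 (1.51 ± 0.29) and the adhesion molecule Vcam1 (1.49 ± 0.30) were higher. The carboxylesterase Ces2a (-1.41 ± 0.12, adjusted p = 1.58e-09), the retinoic acid hydroxylase Cyp26a1 (-2.74 ± 0.46), Cyp7b1 (-1.50 ± 0.28) and Cyp2c29 (-0.85 ± 0.12) were lower. Macrophage markers were higher for 2 of 29, 10 adjusted over the list alone, fatty acid synthesis genes for 4 of 23 and interferon genes for 3 of 20 (adjusted p = 0.138 with an estimated correlation for each). Of 10 male-biased genes 2 were lower (adjusted p = 0.108 with an estimated correlation). The count was 170 without high-fat array 2, 160 without chow array 3, 163 with only the compared groups and 500 without arrays 15 and 17.

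In fat the diet effect covered 4689 genes, 2321 higher and 2368 lower. By probe set 2 Cnr1 was lower on the high-fat diet (-1.06 ± 0.32, adjusted p = 0.0136), while probe set 1 had a change of 0.10 (unadjusted p = 0.363). The call of probe set 2 was lost without chow array 4, when its change was -0.86 with an adjusted p of 0.0591. Of 29 macrophage markers 24 were higher, with Trem2 at 3.50 ± 0.47 and Mmp12 at 4.16 ± 0.52, of 22 cell cycle genes 19 and of 20 inflammatory genes 12 (adjusted p = 0.104, 0.104 and 0.172 with an estimated correlation). Of 23 fatty acid synthesis genes 11 were lower, with the acetyl-CoA carboxylase Acaca at -1.91 ± 0.32 (adjusted p = 0.206 with an estimated correlation). Of 12 gluconeogenesis genes 6 were lower and 1 higher, with Pck1 at -1.09 ± 0.25 (adjusted p = 0.0337 with an estimated correlation, 0.0674 and 0.0523 without chow arrays 1 and 2). Reep6 (-1.92 ± 0.18, adjusted p = 6.7e-08), the transcription factor Zbtb16 (-2.06 ± 0.28) and the naphthalene-oxidizing cytochrome Cyp2f2 (-4.30 ± 0.61) were also lower.

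**Figure D5:**
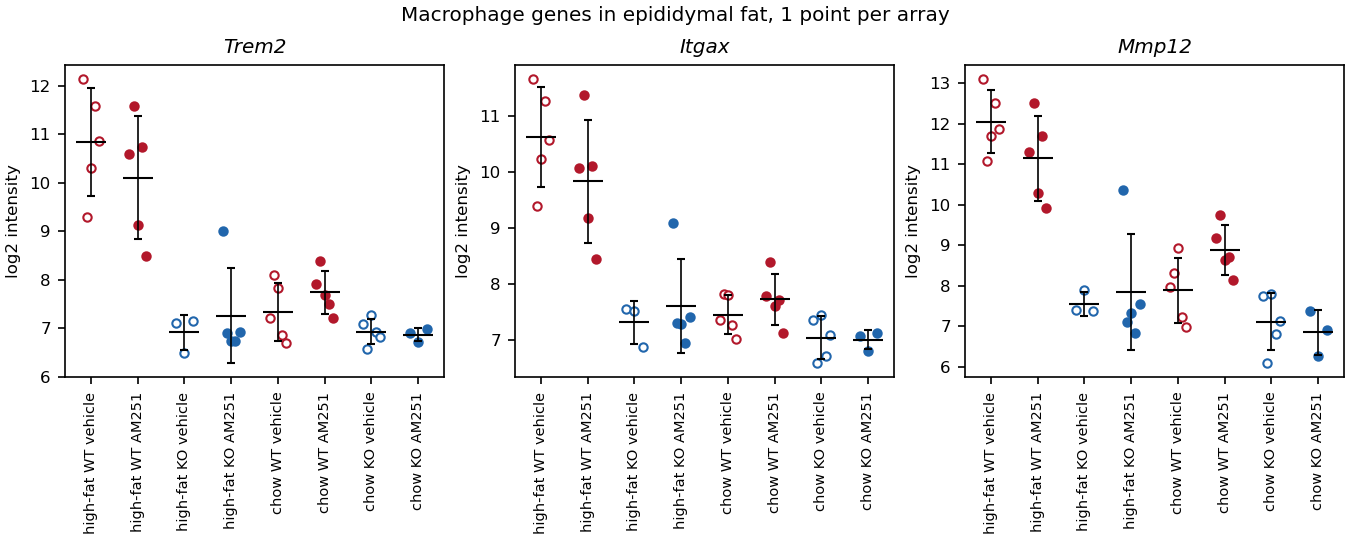
Log2 intensity of the macrophage genes Trem2, Itgax and Mmp12 in each fat array, by diet, genotype and treatment; red points are wild-type and blue points knockout arrays, open points vehicle and filled points AM251, and the bar and whiskers give the mean and SD. On the high-fat diet the open blue points lie below the open red points, with a log2 difference of -3.92 for Trem2, and 1 AM251-treated knockout array lies above the others of its group.

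Across genes, which are not independent replicates, the AM251 effects of pairs of groups that share no array were compared, 10 pairs in all. In livers of high-fat-fed mice the wild-type and knockout effects had a Pearson correlation of -0.035 (Spearman 0.0121) and shared 1 called gene, Cyp2c29. In fat of high-fat-fed mice the correlation between genotypes was -0.287, in fat of chow-fed mice -0.309 and in livers of chow-fed mice 0.242 (Spearman 0.219). In wild-type mice the correlation between diets was 0.258 in liver and 0.14 in fat, and 71% of the 366 genes called in liver on the high-fat diet had the same sign on chow. Between liver and fat of high-fat-fed wild-type mice the correlation was 0.0631 (Spearman -0.00577). There 7 genes rose in both tissues against 0.817 expected by chance and 13 fell in both against 1.24. These expected counts take the tissues as independent, but liver and fat arrays may come from the same mice.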

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

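The tests of the drug-metabolism and synthesis gene patterns and the test of a single array as the whole source of the direction in chow-fed livers were chosen after the results were seen, as were the fit without liver arrays 15 and 17 and the comparison of each array with the genotypes. The other tests of the chow-fed livers and the comparison with other splits were planned.

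The first pattern is the number of genes, 1297, that differed by genotype in chow-fed vehicle livers. Knockout array 17 accounts for part of that number, since 595 genes passed without it. A sample-condition axis shared by several livers cannot be told apart from it, because the change without array 17 and the deviation of that array had a correlation of 0.123 across genes, which decides neither way. For the direction of the 1297 genes, array 17 alone is argued against and the receptor genotype stays open, because 89.7% of them had the same sign among AM251-treated livers, which do not include that array. The median differences were smaller there, 0.10 against 0.40 for the higher and -0.28 against -0.53 for the lower genes. The genes were selected for passing under vehicle, so some fall of the medians in other arrays follows from the selection, by an amount that was not computed. These medians therefore leave the size of the difference uncertain, while its direction may reflect genotype.

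The second pattern is the rise of drug-metabolism genes with AM251 in knockout livers. On the high-fat diet a response that needs CB1 is argued against, provided that the genotype labels hold, since the list rose in mice without it (median 0.30, adjusted p = 0.00276 with an estimated correlation, 0.0511 without vehicle array 44) and Cyp2c29 and Cyp2c55 passed there in every fit with 1 array left out. On chow this stays open (median 0.21, adjusted p = 0.632). Whether the action is shared by both genotypes also stays open: in wild-type livers the list lay at a percentile of 64.46 among random lists on the high-fat diet and 8.05 on chow, and the change of Cyp2c55 was more positive in knockouts (-2.18 ± 0.46, adjusted p = 0.0124), while Cyp2c29 rose in both genotypes on the high-fat diet. Cross-hybridization between Cyp2 paralogs stays open, since the members outside the Cyp2 family reached a percentile of 100 on the high-fat diet but only 80.57 on chow.

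The third pattern is the fall of sterol and fatty acid synthesis genes with AM251 in livers of high-fat-fed wild-type mice. A lower share of hepatocytes is argued against, because the median log2 change of hepatocyte markers was -0.0012 while the synthesis genes had a median of -1.27. In knockout livers on the same diet these genes had a median of 0.0084, so the fall was not seen without the receptor. A need for the receptor and a need for the state of high-fat-fed wild-type livers cannot be told apart. Chow-fed wild-type livers, which have the receptor, gave 0 calls with AM251. High-fat-fed knockout livers already differed from wild-type ones under vehicle, for 228 genes. The fatty acid synthesis median was -0.44 there and the cholesterol synthesis median 0.19. Reduced feeding alone stays open, since the PPARα list lay at a percentile of 100 among random lists, as fasting would give, but the gluconeogenesis and fasting hormone list at a percentile of 0. Food intake was not used here, so an action of AM251 in the liver and one through a fall in food intake cannot be told apart.

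Other splits of the same arrays were compared with each count of AM251 effects. A share of splits under 0.05 was set beforehand as the threshold against chance. It was not adjusted for the number of counts compared. In livers of high-fat-fed wild-type mice 1 of 100 splits gave as many as 366 genes, the real one, and the highest other gave 103, so chance is argued against. In knockouts on that diet 3 of 100 gave as many as 2 (highest other 2). That share is under 0.05, but other splits gave the same count, so chance is not excluded. For the 24 genes of chow-fed knockout livers 8 of 100 splits gave as many (highest other 152), and for the 213 genes in fat of high-fat-fed wild-type mice 9 of 100 (highest other 1268), so chance is not excluded for either. The 3 genes in fat of chow-fed knockouts were reached by 2 of 56 splits. That share is under 0.05, but the highest other split gave 98, so chance is not excluded. With a real count of 0, every split gave as many: 100 of 100 in chow-fed wild-type livers (highest other 3), 56 of 56 in fat of high-fat-fed knockouts (highest other 1) and 100 of 100 in fat of chow-fed wild-type mice (highest other 140). Splits with 152, 1268 and 98 genes, several times the real count, and with 140 genes where the real count was 0 point to a structure of the samples beyond their treatment.

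For the genotype difference of the effect, 2 of 100 splits reached 108 genes in livers of high-fat-fed mice (highest other 338), 100 of 100 reached 0 on chow (39). In fat 5 of 100 reached 78 on the high-fat diet (605) and 17 of 100 reached 1 on chow (690). The share was under 0.05 for the first of these counts only. Since another split gave 338 genes there, chance is not excluded for it or for the others. The splits with 338, 605 and 690 genes again point to a structure of the samples. For the diet difference 1 of 100 reached 48 in liver (29) and 100 of 100 reached 0 in fat (92). For the tissue difference 1 of 100 reached 329 on the high-fat diet (215) and 7 of 100 reached 4 on chow (109). For genotype under vehicle 1 of 100 reached 228 in high-fat-fed livers (183), 2 of 100 reached 1297 in chow-fed livers (1317). Further, 1 of 56 reached 3048 in fat on the high-fat diet (1943) and 7 of 100 reached 11 in fat on chow (257). For diet under vehicle 1 of 100 reached 323 in liver (36) and 1 of 100 reached 4689 in fat (2547). Chance is argued against for the counts reached by 1 of these splits, the real one. It is not excluded for the others, among them the 1297 genes, where another split gave 1317 though the share was under 0.05. The splits with 109 and 257 genes also exceed the real count several times, and a split gave 92 genes where the real count was 0.

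Differences between groups that passed the test of the difference itself were counted for genotype (108 genes in liver and 78 in fat on the high-fat diet, 1 in fat on chow), for diet (48 in liver) and for tissue (329 on the high-fat diet, 4 on chow). Probe sets without a single gene symbol, 13907 in number, were tested on their own. Between AM251 and vehicle 68 of them passed in livers of high-fat-fed wild-type mice, 1 in chow-fed wild-type livers and 22 in chow-fed knockout livers. In fat 7 passed in high-fat-fed wild-type mice, 52 in chow-fed wild-type mice (3 higher and 49 lower) and 2 in chow-fed knockouts. Other splits and alternatives were not run on these probe sets. In chow-fed wild-type fat 0 genes with a symbol passed, and another split of the arrays gave 140. AM251 array 14 of that group had an upper quartile intensity of 170.9, where the other 4 ran from 188.3 to 198.7. Whether the 52 rest on that array was not tested.

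Single arrays lay far from the others of their group in 15 of 156 groups of values tested, where chance gives about 5% and the plotted genes were chosen after their values were seen. In fat of high-fat-fed knockouts given AM251, array 45 had log2 intensities of 9.0 for Trem2, 9.08 for Itgax and 10.36 for Mmp12 against medians of 6.82, 7.30 and 7.22 in the others, and 4.95 for Cnr1 probe set 2 against 6.51. The first 3 values lie in the range of wild-type fat with the same diet and treatment (8.49 to 11.58, 8.45 to 11.37 and 9.93 to 12.50). In liver the array with that number and group had 7.66 for Cyp2b9 against 3.93, in the wild-type range of 5.07 to 9.29. Chow-fed knockout AM251 arrays 22 and 24 also reached 7.245 and 7.063 for Cyp2b9. For Fasn liver array 45 had 9.11, where wild-type arrays ran from 6.01 to 6.57 and knockout arrays from 8.74 to 9.52. On the genes that differ by genotype throughout, chosen without the array and scaled from 0 in wild-type to 1 in knockout mice, liver array 45 lay at 0.818 and fat array 45 at 0.385. Fat arrays ran from -0.628 to 0.645 in wild-type mice and from 0.385 to 1.3 in knockouts. Liver arrays ran from -0.541 to 0.663 and from 0.295 to 1.44, the lowest knockout being chow-fed vehicle array 18. Both tissues overlap, so the score neither decides the genotype of fat array 45 nor sets it apart. The 3 macrophage genes also differed with diet in wild-type fat and do not decide it either. Fat array 45 was kept as labelled, and without it the genotype difference of the AM251 effect in high-fat-fed fat covered 130 genes in place of 78. Array 15 of chow-fed knockout vehicle mice had 6.15 for Cnr1 probe set 2 in fat against 7.09. In liver it had 13.00 for Cyp2c29 against 13.46 and 6.40 for Cyp2c55 against 8.48; array 16 of that group had 11.50 for Pck1 in fat against 12.14. Array 11 of chow-fed wild-type fat with AM251 had 4.84 for Otop1 against 3.64. For Cnr1 in liver, probe set 1 was at 5.51 in high-fat wild-type vehicle array 1 against 5.93 and at 5.66 in chow wild-type vehicle array 5 against 6.01, and probe set 2 at 2.79 in chow knockout AM251 array 23 against 2.70. The mean correlation with other livers was 0.988 for high-fat wild-type vehicle array 2 against 0.991 and 0.986 for chow wild-type vehicle array 3 against 0.991.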

How the results depend on the processing

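The fit without liver arrays 15 and 17 and the count of 84 genes that differ by genotype throughout were chosen after the data were seen. So were the tests of each Cnr1 probe set and the tests of lists with 1 array left out. The other alternatives were planned. Among the values of named genes, 4339 kept their direction and side of the threshold under alternatives other than leaving out an array, 420 kept the direction and lost the call, 1 gained a call and 15 changed sign. With 1 array left out 6165 kept both, 1198 lost the call and 23 changed sign. All sign changes were of Cnr1, at values that had not passed. Of 173 list calls with the preset correlation, 23 were kept with an estimated correlation and 77 with fry.

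With the mean of all probe sets, counts became 6 for AM251 in chow-fed knockout livers, 16 for the genotype difference in chow-fed fat and 17 for genotype in chow-fed fat. With array medians centred the genotype difference in chow-fed fat became 9. Without genes below the median level it became 10, that in high-fat-fed fat 153, genotype in chow-fed fat 21 and the tissue difference on chow 1. With array weights the counts were 625 and 0 for AM251 in high-fat-fed wild-type and chow-fed knockout livers, 230, 294 and 2 for the genotype difference in high-fat-fed liver, high-fat-fed fat and chow-fed fat. They were 588, 276 and 40 for genotype in high-fat-fed liver, chow-fed liver and chow-fed fat. With only the compared groups they were 0 for AM251 in chow-fed knockout livers, 20 in high-fat-fed wild-type fat (16 shared with the 213). They were 163, 39 and 5 for the genotype difference in high-fat-fed liver, high-fat-fed fat and chow-fed fat, 188 and 1 for the tissue difference on high-fat diet and chow. They were 3 and 20 for genotype in chow-fed liver and fat, and 163 for diet in liver. Without arrays 15 and 17 they were 0 for AM251 in chow-fed knockout livers, 1 for the genotype difference in chow-fed livers, 154 for genotype in chow-fed livers, 500 for diet in liver and 7 for the tissue difference on chow. Liver and fat arrays share numbers, and the values leave open whether equal numbers are the same mouse. Over 30 pairs the correlation of residuals ran from -0.123 to 0.199 with a median of 0.0438, 13 of 30 were highest with their own number where 6.67 are expected by chance, and the correlation within numbers was 0.0387. With the number as a replicate block the tissue difference on chow became 8. Called values that moved over 1.5 times with the mean of all probe sets include those of Acaca (-0.97 against -1.91) and Mmp12 (2.53 against 4.16) for diet in fat, Mmp12 (-2.63 against -4.49) for genotype in high-fat-fed fat, and Scd1 (3.35 against 2.18) and Vmn2r96 (0.65 against 1.10) for the tissue difference on high-fat diet and chow. Without arrays 15 and 17 Apob had -0.91 against -1.45 for genotype in chow-fed livers. The causes of these changes were not tested.

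With 1 array left out, AM251 counts ran in liver from 233 to 423 (high-fat wild-type), 0 to 7 (chow wild-type) and 0 to 351 (chow knockout), and in fat from 34 to 632 (high-fat wild-type), 0 to 1 (high-fat knockout), 0 to 11 (chow wild-type) and 0 to 3 (chow knockout). Genotype differences ran from 66 to 136 and 0 to 2 in liver and from 1 to 279 and 1 to 75 in fat (high-fat diet, chow), diet differences from 31 to 69 in liver and 0 to 32 in fat, and tissue differences from 173 to 495 and 3 to 151. Genotype counts under vehicle ran from 75 to 255 and 595 to 1991 in liver and from 1895 to 3270 and 2 to 34 in fat, and diet counts from 160 to 375 in liver. The 84 genes that differ by genotype throughout ranged from 66 to 98 with 1 array left out and from 76 to 102 under the other alternatives.

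Cnr1 changed sign with the mean of all probe sets for genotype in high-fat-fed and chow-fed livers (0.067 and 0.072), AM251 in chow-fed knockout fat (-0.023) and the tissue difference on both diets (-0.42 and -0.40). It did so with quantile normalization for genotype in high-fat-fed livers (0.0077) and the tissue difference on high-fat diet (-0.016), and with array medians centred for AM251 in high-fat-fed wild-type livers (0.0084), genotype in those livers (0.022) and the tissue difference on high-fat diet (-0.0035). With array weights it did so for AM251 in high-fat-fed knockout liver (-0.0038) and fat (0.069), the diet difference in fat (-0.15) and the tissue difference on high-fat diet (-0.032), and without arrays 15 and 17 for AM251 in chow-fed knockout livers (0.020). With 1 array left out Cnr1 ran from -0.10 to 0.019 for AM251 in high-fat-fed wild-type livers, -0.064 to 0.10 in high-fat-fed knockout livers, -0.44 to 0.13 in high-fat-fed knockout fat, -0.12 to 0.048 for the genotype difference in high-fat-fed livers, -0.039 to 0.47 for the diet difference in fat, -0.039 to 0.11 for the tissue difference on high-fat diet, and -0.11 to 0.054 and -0.13 to 0.028 for genotype in high-fat-fed and chow-fed livers. The cause was not tested.

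The percentage of called genes that were higher moved by more than 10 points with the scaling in 6 comparisons. It was 23.4% with quantile normalization against 34.3% for the genotype difference in high-fat-fed livers, 55.5% against 43.2% for AM251 in high-fat-fed wild-type fat and 59.9% against 46.5% for the tissue difference on high-fat diet. With array medians centred it was 61.6% against 40.4% for genotype in high-fat-fed livers, 33% against 43.4% in chow-fed livers and 22.2% against 0% for the genotype difference in chow-fed fat. Signal over background, for which no level was computed here, limits what the arrays show for dim probe sets.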

Other observations

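The selection of genes that differ by genotype throughout, its comparison with other splits of the arrays, the correlations between AM251 and genotype effects and the medians by pair of groups were chosen after the data were seen; the test of linked alleles was written before its result.

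Some genes differed between knockout and wild-type mice in the same direction in both tissues, both diets and both treatments, in pooled tests of each tissue and in each of the 8 pairs of groups. There were 84, of which 50 were higher and 34 lower in knockouts. Among the higher, the transcription factor Zbtb16 had a pooled log2 difference of 1.10 in liver and 0.99 in fat, the chaperone Fkbp5 0.72 and 0.40, and the transcription factor Klf15 0.21 and 0.81. The asparagine synthetase Asns had 0.72 and 0.69, the phosphatidate phosphatase Lpin1 0.90 and 0.28, the vasopressin receptor Avpr1a 0.99 and 0.43, and the sterol reductase Tm7sf2 0.69 and 0.53. Lower in knockouts were the sterol-binding protein Osbpl3 (-1.48 and -0.47), the cholesterol ester hydrolase Nceh1 (-0.42 and -1.29), the kinetochore protein Spc25 (-0.54 and -1.04), the hormone Fgf21 (-0.86 and -0.36) and the heat shock proteins Hsph1 (-0.53 and -0.59) and Hspb1 (-0.57 and -0.38). Of 100 splits of the arrays within tissue, diet and treatment, 1 gave as many as 84, the real one, and the highest other gave 0. Chance is argued against for splits that treat the tissues as independent. Liver and fat arrays with the same number, which may be the same mouse, were not kept together in these splits.

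In the pooled tests 923 genes differed by genotype in liver and 4252 in fat. In liver 14 of 19 cholesterol synthesis genes were higher in knockouts, with a median of 0.46, and 16 of 26 PPARα targets lower, with a median of -0.27 (adjusted p = 0.0112 and 0.0102 with an estimated correlation). Most of this came from AM251-treated mice on the high-fat diet, with medians of 1.57 and -0.68. The medians were 0.19 and -0.19 on that diet under vehicle, and 0.05 and -0.16 under vehicle and -0.01 and -0.09 under AM251 on chow. Of 14 glucocorticoid-responsive genes 4 were higher in liver, and 5 were higher and 3 lower in fat (adjusted p = 0.176 and 0.513 with an estimated correlation). In fat 15 of 23 fatty acid synthesis genes and 26 of 33 oxidative phosphorylation genes were higher, and 21 of 29 macrophage markers lower (adjusted p = 0.068 with an estimated correlation for each list). The macrophage median ran from -1.09 in high-fat-fed vehicle mice to -0.05 in chow-fed vehicle mice, and the fatty acid synthesis median from 0.15 in the latter to 1.13 in chow-fed mice given AM251. The lists of genes for insulin signalling, endocannabinoid receptors and enzymes, unfolded protein response, brown adipocytes, lymphocytes, stellate cells and epididymis gave 0 calls with an estimated correlation in any AM251 effect.

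One candidate explanation for the 84 genes is that alleles of the strain in which the deletion was made are still linked to the receptor locus. Of the 200 measured genes nearest to Cnr1, 2 were among the 84 (1% against 0.429% elsewhere, ratio 2.33, two-sided Fisher exact p = 0.216), which leaves linked alleles undecided for those genes and leaves 81 genes elsewhere.

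On the high-fat diet the effect of AM251 in wild-type mice resembled the genotype difference under vehicle, but both share the wild-type vehicle arrays. In liver the correlation across genes was 0.509, against 0.47 in 100 simulations of noise with shared arrays and no true change. The covariance was 0.0217 against 0.00871. Over 20 divisions of the vehicle arrays into separate controls the median correlation was 0.295 (0.136 to 0.439). In fat the correlation was 0.579 against 0.434 and the covariance 0.0473 against 0.0111, with a median correlation of 0.41 (0.0373 to 0.51) over such divisions. Because the simulations hold no true change, their correlation does not give the share that is due to the shared arrays. The genes called for genotype under vehicle kept their sign among AM251-treated mice for 82% of 228 genes in livers and 91.3% of 3048 genes in fat on the high-fat diet, and for 45.5% of 11 genes in fat on chow. Among AM251-treated livers on the high-fat diet the medians were 0.13 against 0.63 for the higher and -0.33 against -0.75 for the lower genes. In high-fat-fed fat they were 0.32 against 0.55 and -0.35 against -0.62. These genes were selected for passing under vehicle, so some fall of the medians in other arrays follows from the selection. Its size was not computed, so selection and an effect of AM251 cannot be told apart here. Over all genes the 2 genotype differences correlated at 0.3 in high-fat-fed livers, 0.712 in high-fat-fed fat and 0.104 in chow-fed fat.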
